A study of Drosophila melanogaster with 17 samples.

How the data were processed

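Polyadenylated RNA was sequenced from heads and guts of mated male flies kept at 25 °C, 60% humidity and 12 h light and 12 h dark, with 20 flies per vial, and sampled at ZT8. The 17 libraries made 7 groups, namely w1118 and orco2 heads at day 3 and day 40 (2 libraries each) and w1118, orco2 and per01 guts at day 40 (3 libraries each), and all were used. The deposited tables hold raw read counts per gene, 1 table per tissue, which the authors made, per the submitters' processing notes, with fastp, HISAT2 and featureCounts against dm6 before using DESeq2. The notes give no annotation release and no setting for strand or for reads that map to several places, so counts of near-identical copies (Hsp70, Lys, Cyp12d1, AttA and AttB, transposon insertions) and of overlapping or antisense genes are uncertain. The head table had 23882 features, 5416 of them transposon insertions, while that of the guts held 18354 features and 0 insertions. Of these, 81 and 79 matched no gene in the BDGP6 annotation or name table and were tested under their own identifiers, and 5464 and 2385 had no count. The 38 mitochondrial genes were listed at 0 counts in both tables. Of counts from 1 to 20, 60.3 to 75.5% per library were even numbers, so intervals that treat counts as independent may be too narrow.

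Total counts ran from 25792664 to 41693684 per library, and a count of 3 over a group was taken as the floor. Each tissue was fitted alone with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group with a minimum count of 10, glmQLFit and glmQLFTest, group means without covariates), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The comparisons were orco2 against w1118 heads at each age, day 40 against day 3 heads in each genotype, the age by genotype interaction, and the 3 pairs of gut groups, so each pooled the spread of all libraries of its tissue. The median gene dispersion was 0.0282 in heads and 0.176 in guts. CPM are TMM-scaled, and folds against a group with no counts are bounds from the floor over the group, while a group with 1 to 3 counts gets a ratio with an exact 95% interval. A total of 32 gene lists were written before the data were examined, as were the groups, tests, alternatives and rule for naming genes, and 978 entries were matched and 9 were not (BaraA2, Hop, Cyp6a21, Tor, esg, Dl, hdc, OatP58Dc and Peb). They cover the clock, smell, vision, immunity, stress, metabolism, gut cell types and functions, cuticle and other tissues. Lists of at least 5 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01, and again with an estimated one) and with fry, which tests only whether members move one way. Some genes belong to more than 1 list, such as apolpp, FASN1 and Desat1 (fat body and lipid), tobi (digestive and insulin) and several peptides (neuropeptide and enteroendocrine).

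The genes named in each comparison were Orco, per and w, then the 6 highest and 6 lowest fold changes among genes with adjusted p under 0.05, a mean of at least 5 CPM and no overlap of libraries (4 and 4 without the last condition for the interaction). Up to 4 members with the smallest p of each called list, in its direction, and every core clock member that passed were named too. Other names, given where 5 or fewer members make up a count or as examples of an overlap or list, were chosen after their values were seen. Chance overlaps are the product of the counts of calls over the genes tested. The fits were tested on simulated data with the real dispersions. With 100 genes changed 2-fold and 100 changed 4-fold, edgeR recovered 38 to 46 and 72 to 78 in the 4 head comparisons, 9 and 65 in the interaction, and 0 and 0 in the guts, where DESeq2 1.42.0 recovered 6 to 10 and 55 to 62. A design with 50 genes at each of 2-, 4-, 16- and 64-fold was added after that result, and edgeR recovered 0 to 1, 11 to 14, 32 to 37 and 42 to 43 of 50 in the guts. Unchanged genes had p under 0.05 in 4.24 to 4.84% of cases. Over both designs false calls numbered 9 to 28 in heads and 0 to 11 in guts with edgeR, and 31 to 59 and 53 to 83 with DESeq2. Alternatives were DESeq2 size factors, no count filter, the DESeq2 Wald test, limma-voom, only the libraries of the 2 groups, a fold threshold, a replicate block, each library left out in turn, and 3 added after the data were seen, which are named as such in the closing part. Where a library was left out of a group of 2, the lone library was assumed to vary like the other groups.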

Results

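Polyadenylated RNA was sequenced from heads and guts of mated male Drosophila melanogaster sampled at ZT8, 8 h after lights on. Heads came from w1118 flies, which lack white function, and from orco2 mutants, at day 3 and day 40, with 2 libraries per group. Guts came from w1118, orco2 and per01 flies at day 40, with 3 libraries per group. The head libraries held 30077774 and 31560513 for w1118 and 29447898 and 27082849 counts for orco2 at day 3. At day 40 they held 32970825 and 33932201 for w1118 and 30371987 and 30178115 for orco2. The gut libraries held 39862078, 32787343 and 25792664 counts for w1118, 41693684, 33203514 and 39111606 for orco2 and 34802305, 28204738 and 33552229 for per01. Sizes are log2 fold changes ± SE from the edgeR fits, levels are means ± SD in CPM (counts per 1e+06 counts, scaled by TMM), and a gene rose, fell or changed when its adjusted p was under 0.05. The p-values measure only the spread between these libraries, which may be technical. Intervals and floors cover counting error only.

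Orco (FBgn0037324, chromosome 3R, 5407183 to 5412406, BDGP6), the co-receptor that odorant receptors need, was read at 251 and 205 counts in the day 3 w1118 heads and at 45 and 46 in the orco2 heads. At day 40 the counts were 90 and 105 against 24 and 33. Orco was thus lower in orco2 at day 3 (1.63 ± 0.123 against 6.997 ± 1.14 CPM, -2.10 ± 0.28, adjusted p = 0.00427 by edgeR) and at day 40 (1.02 ± 0.207 against 2.82 ± 0.316 CPM, -1.47 ± 0.29, adjusted p = 0.0174). In the guts Orco stayed near the floor, with 0, 14 and 0 counts in w1118, 0, 13 and 2 in orco2 and 17, 0 and 0 in per01, so it gave no check of the gut labels there. The clock repressor gene per (FBgn0003068, chromosome X, 2685580 to 2692780) had 4414 and 4525 counts in day 3 w1118 heads, 1917 and 1411 in day 3 orco2 heads, 6344 and 6251 in day 40 w1118 heads and 1442 and 1436 in day 40 orco2 heads. In the guts per had 1415, 3086 and 1603 counts in w1118, 535, 364 and 379 in orco2 and 760, 673 and 783 in per01. The per01 allele is a nonsense mutation, so the per level does not check that label. The gene w (FBgn0003996, chromosome X, 2790599 to 2796466), which encodes an ABC transporter of eye pigment precursors, had 1 and 0 counts in day 3 w1118 heads and 13 and 8 at day 40, against 934 and 851 and 605 and 525 in orco2. Its gut counts were 25, 28 and 0 in w1118, 571, 311 and 394 in orco2 and 149, 94 and 64 in per01. Both mutants carried more w transcript than w1118, higher in the gut by 4.42 ± 0.996 in orco2 (adjusted p = 0.0176) and 3.21 ± 0.95 in per01 (adjusted p = 0.0477).

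The first question was how the heads of young orco2 flies differed from those of w1118 (day 3, 2 libraries against 2). 891 of 12243 tested genes changed, 594 of them higher and 297 lower, 627 of them by at least 2-fold. 4 clock genes fell in orco2, namely tim (-1.88 ± 0.18, adjusted p = 0.00109), vri (-1.39 ± 0.11, adjusted p = 0.000582), per (59.3 ± 9.25 against 137 ± 0.341 CPM, -1.21 ± 0.12, adjusted p = 0.0014) and cwo (-0.96 ± 0.13, adjusted p = 0.00405). The proteins PER and TIM repress the transcription that CLK and CYC drive, and vri and cwo encode further repressors in the clock. Of the 16 core clock genes, 0 rose, 4 fell and 12 did not pass (2 and 4 adjusted over the list alone, camera adjusted p = 0.0297, adjusted p = 0.645 with an estimated correlation). Among 11 antennal ionotropic receptor genes, 0 rose and 3 fell while 8 did not pass (0 and 5 adjusted over the list alone, camera adjusted p = 0.000386, adjusted p = 0.458 with an estimated correlation). Ir75a (-5.05 ± 0.51) and Ir75b (-4.23 ± 0.40), which encode antennal acid receptors, and Ir76a (-1.26 ± 0.21) were the 3 that fell. 12 of the 33 phototransduction genes rose, 2 fell and 19 did not pass (15 and 2 adjusted over the list alone, camera adjusted p = 3.99e-05, adjusted p = 0.458 with an estimated correlation). The R8 rhodopsin gene Rh6 (1.31 ± 0.15), pinta (0.9999 ± 0.14), stops (0.77 ± 0.11) and the channel gene trp (0.57 ± 0.09) rose, while laza and trpl fell. Of the 37 antimicrobial peptide and immune effector genes, 10 rose, 0 fell and 27 did not pass (21 and 0 adjusted over the list alone, camera adjusted p = 0.000213, adjusted p = 0.458 with an estimated correlation). The Toll-induced Bomanin genes BomBc1 (2.98 ± 0.41), BomBc2 (2.70 ± 0.40), BomT2 (1.73 ± 0.20) and BomS2 (1.33 ± 0.18) were among those that rose. The Imd-regulated DptA stood at 138 and 5.795 CPM in the 2 orco2 libraries and 0 in w1118, which is at least 1629.7-fold higher against a floor of 3 counts over the group, and Dro rose as well (10.11 ± 2.09).

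Camera also called fat body genes higher as a list in the day 3 orco2 heads. 10 of the 18 fat body genes rose, 0 fell and 8 did not pass (13 and 0 adjusted over the list alone, camera adjusted p = 1.03e-06, adjusted p = 0.531 with an estimated correlation). Those with the smallest p were apolpp (1.82 ± 0.21), which encodes the apolipophorin precursor, fit (3.99 ± 0.46) and the storage protein genes Lsp1beta (3.93 ± 0.47) and Lsp2 (4.15 ± 0.60). The summed level of the fat body list was 8865 and 12550.1 CPM in the orco2 libraries and 3437 and 4201 CPM in w1118. Among 32 lipid metabolism genes, 7 rose and 1 fell while 24 did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 3.99e-05, adjusted p = 0.645 with an estimated correlation). The diacylglycerol acyltransferase gene mdy (1.67 ± 0.18), the fatty acid synthase gene FASN1 (1.03 ± 0.19) and Desat1 (1.17 ± 0.23) rose and Npc2b fell, and 3 genes of this list (apolpp, FASN1 and Desat1) belong to the fat body list too. Of the 51 glutathione transferase and P450 genes, 14 rose, 2 fell and 35 did not pass (21 and 2 adjusted over the list alone, camera adjusted p = 3.16e-05, adjusted p = 0.645 with an estimated correlation). Cyp4e3 (2.46 ± 0.13), Cyp309a1 (3.44 ± 0.23), Cyp309a2 (3.19 ± 0.23) and Cyp12d1-p (4.34 ± 0.38) rose, whereas Cyp6a17 (-6.30 ± 0.38) and GstE4 fell. For the 81 cytosolic ribosomal protein genes, 24 rose, 0 fell and 57 did not pass (60 and 0 adjusted over the list alone, camera adjusted p = 1.44e-22, adjusted p = 0.645 with an estimated correlation). RpL12 (0.61 ± 0.11), RpS21 (0.81 ± 0.15), RpLP1 (0.94 ± 0.19) and RpS18 (0.77 ± 0.15) had the smallest p. Among 22 heat shock protein genes, 1 rose and 0 fell while 21 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.0332, adjusted p = 0.645 with an estimated correlation). Hsp70Ab (3.67 ± 0.61) was the member that rose. Of the 65 oxidative phosphorylation genes, 0 rose, 0 fell and 65 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.029, adjusted p = 0.875 with an estimated correlation). That list was called higher as a set. Among single genes, w was 2086-fold higher (exact 95% interval 374 to 82433) in orco2, an insertion of the transposon INE-1 was at least 254-fold higher, and Ugt37B1 (8.38 ± 0.61) and CG30428 (7.58 ± 0.62) rose. The insertion S{}AGO2[S1008] was at least 738-fold lower, and fiz (-5.59 ± 0.51), lncRNA:CR45973 (-5.51 ± 0.79), CG9150 (-4.65 ± 0.56) and Ugt302K1 (-4.27 ± 0.35) fell. Camera called 10 of 32 lists, 8 higher and 2 lower, and 0 with an estimated correlation (smallest p = 0.458). The test had few libraries, and without w1118 replicate 1 or 2 the count of changed genes was 278 or 345, against 3246 without orco2 replicate 1. That orco2 replicate held the gut enzyme transcript alphaTry at 126 CPM, and the other held 0.

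The same genotypes were compared in old heads (day 40, 2 libraries against 2). 1586 of 12243 tested genes changed, 987 of them higher and 599 lower, 768 of them by at least 2-fold. 5 clock genes fell in orco2, namely tim (-2.35 ± 0.18, adjusted p = 0.000447), vri (-1.99 ± 0.11, adjusted p = 0.000123), per (51.5 ± 1.20 against 182 ± 1.33 CPM, -1.82 ± 0.13, adjusted p = 0.0003), cwo (-1.02 ± 0.13) and the activator gene Pdp1 (-0.84 ± 0.18). Among 16 core clock genes, 0 rose and 5 fell while 11 did not pass (3 and 5 adjusted over the list alone, camera adjusted p = 0.036, adjusted p = 0.632 with an estimated correlation). 11 of the 37 antimicrobial peptide and immune effector genes rose, 0 fell and 26 did not pass (13 and 0 adjusted over the list alone, camera adjusted p = 1.65e-08, adjusted p = 0.423 with an estimated correlation). BaraA1 (2.25 ± 0.19), BomS2 (2.01 ± 0.18), BomT2 (2.04 ± 0.20) and BomBc1 (3.87 ± 0.41) had the smallest p. Of the 34 Toll and Imd pathway genes, 8 rose, 1 fell and 25 did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 0.00419, adjusted p = 0.466 with an estimated correlation). The peptidoglycan recognition genes PGRP-SB1 (2.79 ± 0.32), PGRP-SD (1.19 ± 0.23), PGRP-LA (0.77 ± 0.12) and PGRP-LC (0.62 ± 0.12) rose and imd fell. For the 36 odorant binding and olfactory support genes, 8 rose, 3 fell and 25 did not pass (10 and 3 adjusted over the list alone, camera adjusted p = 0.0372, adjusted p = 0.763 with an estimated correlation). Obp8a (2.58 ± 0.16), Obp44a (1.38 ± 0.15), Obp57a (2.14 ± 0.30) and Obp99c (1.98 ± 0.31) rose, while Obp99a, Obp56h and Obp19c fell. Among 22 heat shock protein genes, 4 rose and 0 fell while 18 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 5.29e-05, adjusted p = 0.423 with an estimated correlation). Hsp70Ab (5.20 ± 0.53), Hsp70Aa (4.31 ± 0.48), Hsp68 (0.87 ± 0.12) and Hsp26 (1.69 ± 0.25) were the 4 that rose, and reads of the near-identical Hsp70 copies may be shared among them. Of the 20 neuron and synapse genes, 0 rose, 3 fell and 17 did not pass (0 and 10 adjusted over the list alone, camera adjusted p = 5.29e-05, adjusted p = 0.602 with an estimated correlation). The calcium channel gene cac (-1.89 ± 0.21), futsch (-0.76 ± 0.19) and the active zone gene brp (-0.70 ± 0.18) fell.

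The detoxification, ribosomal and lipid lists were called higher in the day 40 orco2 heads. 22 of the 51 glutathione transferase and P450 genes rose, 2 fell and 27 did not pass (31 and 2 adjusted over the list alone, camera adjusted p = 2.08e-11, adjusted p = 0.466 with an estimated correlation). GstE1 (3.02 ± 0.22), Cyp12d1-p (4.62 ± 0.34), Cyp6a8 (6.41 ± 0.55) and Cyp12d1-d (7.88 ± 0.77) had the smallest p, and Cyp6a17 (-5.46 ± 0.36) fell again. Of the 81 cytosolic ribosomal protein genes, 57 rose, 0 fell and 24 did not pass (73 and 0 adjusted over the list alone, camera adjusted p = 6.41e-25, adjusted p = 0.466 with an estimated correlation). RpS21 (0.99 ± 0.15), RpS13 (0.74 ± 0.12), RpL35A (0.74 ± 0.12) and RpL27A (0.82 ± 0.13) led this list. Among 65 oxidative phosphorylation genes, 17 rose and 0 fell while 48 did not pass (36 and 0 adjusted over the list alone, camera adjusted p = 2.29e-12, adjusted p = 0.466 with an estimated correlation). ATPsynC (0.49 ± 0.09), ND-13A (0.78 ± 0.15), ND-13B (0.69 ± 0.14) and ATPsynCF6 (0.55 ± 0.12) rose. For the 32 lipid metabolism genes, 14 rose, 0 fell and 18 did not pass (18 and 0 adjusted over the list alone, camera adjusted p = 1.97e-07, adjusted p = 0.466 with an estimated correlation). mdy (1.80 ± 0.18), bmm (1.16 ± 0.14), Lsd-2 (1.01 ± 0.13) and Mtp (1.03 ± 0.15) rose, bmm encoding a triglyceride lipase and Lsd-2 a perilipin. 8 of the 18 fat body genes rose, 1 fell and 9 did not pass (8 and 1 adjusted over the list alone, camera adjusted p = 0.00147, adjusted p = 0.552 with an estimated correlation). fon (1.89 ± 0.17), Lst (1.44 ± 0.18), apolpp (1.20 ± 0.20) and Lsp2 (3.26 ± 0.56) rose and the yolk protein gene Yp3 fell. The summed level of the fat body list was 25249 and 21272 CPM in orco2 and 9711 and 11859.5 CPM in w1118. Among 13 Malpighian tubule genes, 0 rose and 0 fell while 13 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.466 with an estimated correlation). That set was called lower. Among single genes an insertion of the hoppel element was at least 469-fold higher, CG30428 was 1024-fold higher (exact 95% interval 183 to 40482), CG30091 was 652-fold higher (exact 95% interval 180.1 to 5394) and CG3117 rose (6.24 ± 0.83). CG3397 was at least 546-fold lower and S{}AGO2[S1008] at least 339-fold lower, while the alpha-glucosidase gene tobi (-6.93 ± 0.71), CG9150 (-5.16 ± 0.58) and Ir75a (-5.12 ± 0.46) fell. Camera called 12 of 32 lists, 9 higher and 3 lower, and 0 with an estimated correlation (smallest p = 0.423). Without w1118 replicate 1 or 2 the count of changed genes was 319 or 735, and without orco2 replicate 1 or 2 it was 356 or 475. The w1118 replicate 2 library held alphaTry at 69.8 CPM, against 0 in replicate 1.

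Genes that changed at both ages in orco2 heads were then counted. 626 genes changed the same way at day 3 and day 40, 438 higher and 188 lower, against 47.9 and 14.53 by chance. The pair of comparisons shared no libraries. Their fold changes over all tested genes correlated at only 0.258, or -0.0047 with the DESeq2 Wald test. 4 genes changed in opposite directions against 53.01 by chance, namely Nha2, CG8132, a hopper2 insertion and CG17350. Among those that fell at both ages were per, tim, vri, cwo, Orco, Ir75a, Cyp6a17 and CG9150, and among those that rose were w, CG30428, mdy, apolpp, Lsp2 and BomS2.

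**Figure D1:**
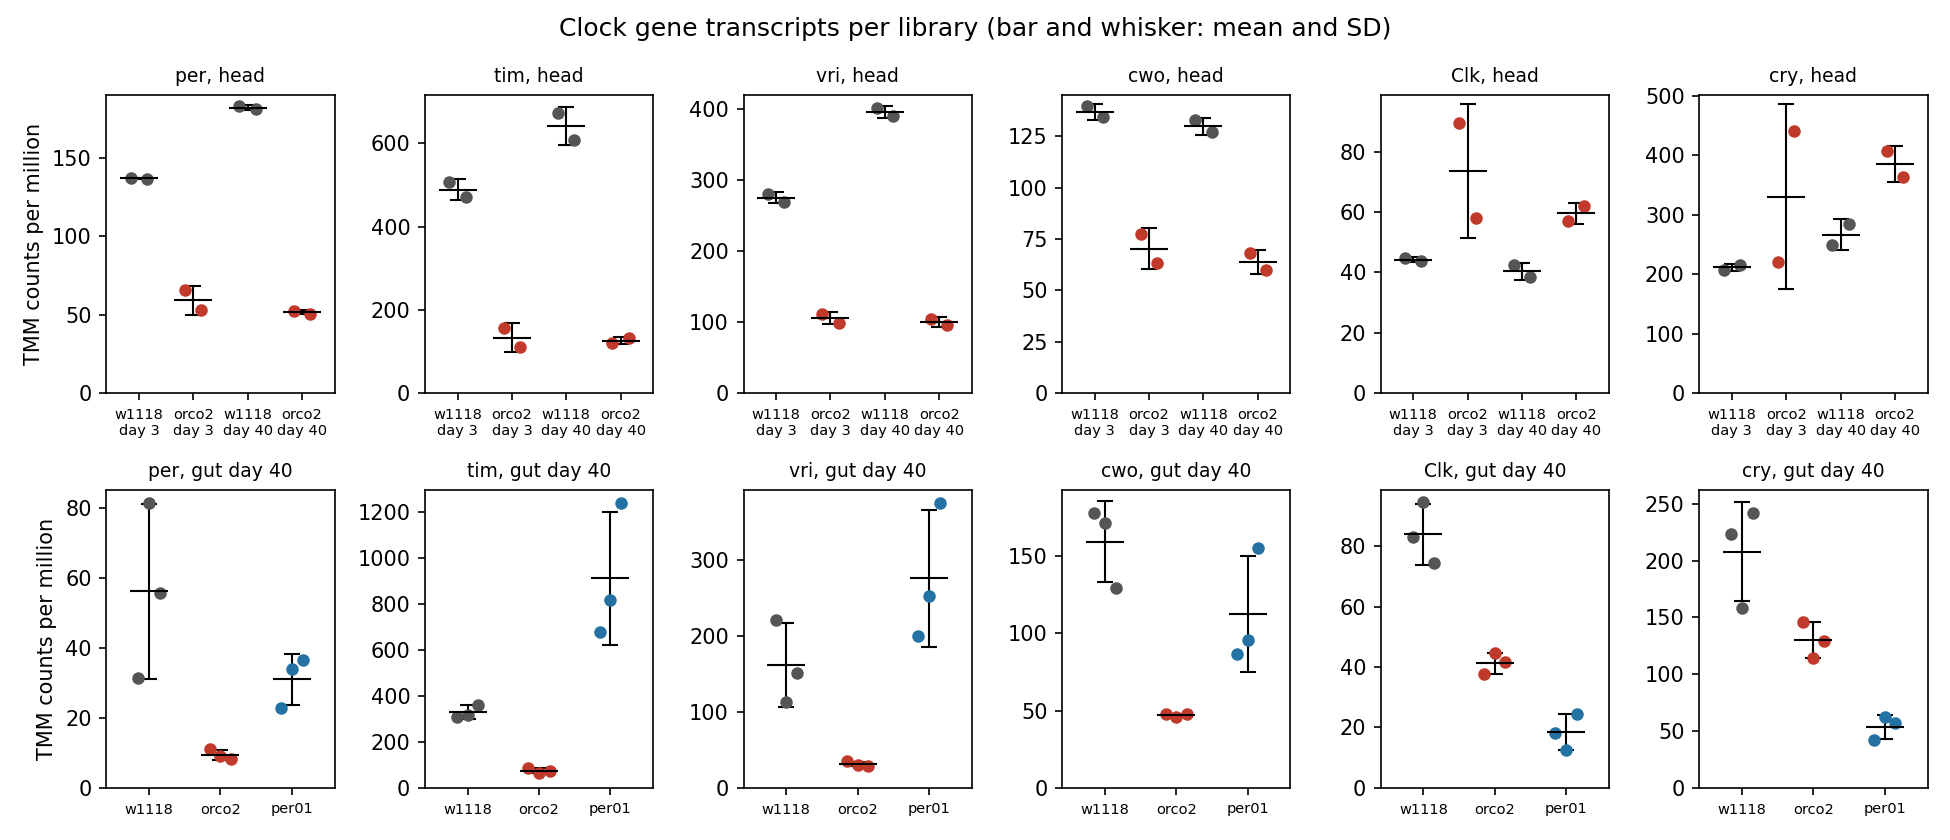
Levels of per, tim, vri, cwo, Clk and cry (CPM, y axis) in each library of the 4 head groups (top) and the 3 gut groups at day 40 (bottom), each point a library and each bar and whisker the mean ± SD. In day 40 heads per stood at 51.5 CPM in orco2 and 182 CPM in w1118.

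The change with age was examined in w1118 heads (day 40 against day 3, 2 libraries against 2). 1933 of 12243 tested genes changed, 1048 of them higher and 885 lower, 801 of them by at least 2-fold. Of the 37 antimicrobial peptide and immune effector genes, 22 rose, 0 fell and 15 did not pass (32 and 0 adjusted over the list alone, camera adjusted p = 1.14e-09, adjusted p = 0.15 with an estimated correlation). BomS1 (1.31 ± 0.11), Dso1 (1.59 ± 0.14), BomT2 (2.15 ± 0.20) and BomT3 (1.13 ± 0.13) had the smallest p. DptA was at least 3075-fold higher at day 40, with 228 and 54.1 CPM in its 2 libraries and 0 at day 3, and Dro (10.71 ± 2.10), DptB (9.02 ± 1.72) and AttC (7.99 ± 1.46) and PGRP-SC2 (7.04 ± 1.39) were the other immune genes among the highest. Among 34 Toll and Imd pathway genes, 13 rose and 0 fell while 21 did not pass (17 and 0 adjusted over the list alone, camera adjusted p = 1.3e-07, adjusted p = 0.15 with an estimated correlation). PGRP-SD (2.82 ± 0.25), PGRP-SB1 (3.94 ± 0.35), PGRP-LF (1.86 ± 0.21) and Tab2 (0.95 ± 0.11) led it. 4 of the 12 Turandot and JAK-STAT genes rose, 0 fell and 8 did not pass (6 and 0 adjusted over the list alone, camera adjusted p = 0.00465, adjusted p = 0.295 with an estimated correlation). The stress-induced TotA (2.79 ± 0.50), TotX (1.07 ± 0.22) and TotC (3.58 ± 0.92) and et (0.85 ± 0.23) were the 4 that rose. For the 18 fat body genes, 13 rose, 0 fell and 5 did not pass (14 and 0 adjusted over the list alone, camera adjusted p = 1.75e-08, adjusted p = 0.282 with an estimated correlation). Lsp1alpha (10.03 ± 0.49), Lst (2.36 ± 0.19), Tsf1 (2.43 ± 0.23) and Yp3 (1.36 ± 0.15) rose, and the summed fat body list was 9711 and 11859.5 CPM at day 40 against 3437 and 4201 at day 3. Of the 32 lipid metabolism genes, 11 rose, 0 fell and 21 did not pass (16 and 0 adjusted over the list alone, camera adjusted p = 6.31e-07, adjusted p = 0.338 with an estimated correlation). bmm (0.98 ± 0.14), Mtp (1.01 ± 0.15) and apolpp (1.22 ± 0.20) rose. Among 51 glutathione transferase and P450 genes, 17 rose and 1 fell while 33 did not pass (23 and 1 adjusted over the list alone, camera adjusted p = 3.07e-06, adjusted p = 0.552 with an estimated correlation). Cyp309a1 (3.81 ± 0.23), Cyp4e3 (1.76 ± 0.13), Cyp309a2 (2.91 ± 0.23) and Cyp6d2 (3.90 ± 0.36) rose and GstD11 fell. 5 of the 22 genes of reactive oxygen species handling rose, 1 fell and 16 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.0185, adjusted p = 0.611 with an estimated correlation). Irc (1.38 ± 0.17), cnc (0.63 ± 0.10), Gclc (0.38 ± 0.10) and Prx4 (0.89 ± 0.24) rose and the mitochondrial superoxide dismutase gene Sod2 fell. Of the core clock list, vri (0.53 ± 0.11, adjusted p = 0.0175) and the neuropeptide gene Pdf (0.73 ± 0.16, adjusted p = 0.0218) rose, and Orco fell (-1.31 ± 0.27, adjusted p = 0.0168).

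Camera called the muscle, mitochondrial, neuronal and cuticle lists lower with age in w1118 heads. 0 of the 24 muscle genes rose, 16 fell and 8 did not pass (0 and 17 adjusted over the list alone, camera adjusted p = 3.34e-13, adjusted p = 0.282 with an estimated correlation). Mlc2 (-1.94 ± 0.10), Mlc1 (-1.95 ± 0.11), Tm2 (-1.38 ± 0.12) and up (-1.43 ± 0.13) fell, Mlc1 and Mlc2 encoding myosin light chains. Of the 65 oxidative phosphorylation genes, 0 rose, 45 fell and 20 did not pass (0 and 57 adjusted over the list alone, camera adjusted p = 6.93e-26, adjusted p = 0.282 with an estimated correlation). ATPsynC (-1.20 ± 0.09), ATPsynbeta (-1.12 ± 0.11), blw (-1.09 ± 0.12) and ND-42 (-0.94 ± 0.11) had the smallest p, the first 3 of them ATP synthase subunits. Among 20 neuron and synapse genes, 0 rose and 8 fell while 12 did not pass (0 and 10 adjusted over the list alone, camera adjusted p = 1.63e-08, adjusted p = 0.338 with an estimated correlation). Gad1 (-1.34 ± 0.10), ple (-0.96 ± 0.13), Snap25 (-0.74 ± 0.12) and ChAT (-0.84 ± 0.15) fell, among them the genes for glutamate decarboxylase, tyrosine hydroxylase and choline acetyltransferase. 0 of the 28 adult cuticle protein genes rose, 8 fell and 20 did not pass (1 and 10 adjusted over the list alone, camera adjusted p = 3.22e-06, adjusted p = 0.15 with an estimated correlation). Vajk2 (-3.63 ± 0.19), Vajk3 (-3.83 ± 0.36), Cpr49Ae (-1.72 ± 0.19) and Cpr62Bc (-3.11 ± 0.43) fell. Of the 81 cytosolic ribosomal protein genes, 59 rose, 0 fell and 22 did not pass (72 and 0 adjusted over the list alone, camera adjusted p = 3.22e-24, adjusted p = 0.334 with an estimated correlation). RpL18 (0.98 ± 0.11), RpL35 (0.98 ± 0.11), RpS26 (1.15 ± 0.14) and RpL3 (0.77 ± 0.10) rose. Among 27 digestive enzyme genes, 7 rose and 0 fell while 20 did not pass (7 and 0 adjusted over the list alone, camera adjusted p = 0.00171, adjusted p = 0.57 with an estimated correlation). Of the day 40 libraries only replicate 2 held the trypsin gene alphaTry (69.8 CPM, 0 in replicate 1), and without replicate 2 the list was still called but its median went from 5.001 to 0.25. The lysosomal protease gene cathD (1.22 ± 0.15), tobi (3.30 ± 0.56) and LManI (1.05 ± 0.22) rose, and mag was at least 21.7-fold higher. For the 20 enterocyte and septate junction genes, 5 rose, 0 fell and 15 did not pass (7 and 0 adjusted over the list alone, camera adjusted p = 0.024, adjusted p = 0.321 with an estimated correlation). srp (1.49 ± 0.19), Gli (0.62 ± 0.10), Myo31DF (0.84 ± 0.14) and Mcr (0.37 ± 0.10) and cora were the 5 that rose. The genes with the lowest fold changes were CG7214 (-9.17 ± 0.37), Acp1 (-7.76 ± 0.67), CG31904 (-7.17 ± 0.23), Crys (-5.46 ± 0.46) and CG8736 (-5.13 ± 0.47), and CG11458 was 408-fold lower (exact 95% interval 113 to 3375). The gene w was 19.8-fold higher (exact 95% interval 3.19 to 819.6) at day 40, from 1 count at day 3. Camera called 14 of 32 lists, 10 higher and 4 lower, and 0 with an estimated correlation (smallest p = 0.15). Without day 3 replicate 1 or 2 the count of changed genes was 447 or 575, and without day 40 replicate 1 or 2 it was 936 or 572.

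The change with age was examined in orco2 heads in the same way (2 libraries against 2). 2968 of 12243 tested genes changed, 1570 of them higher and 1398 lower, 1095 of them by at least 2-fold. 21 of the 37 antimicrobial peptide and immune effector genes rose, 0 fell and 16 did not pass (25 and 1 adjusted over the list alone, camera adjusted p = 9.05e-12, adjusted p = 0.114 with an estimated correlation). BomS1 (2.03 ± 0.11), BomS3 (2.18 ± 0.13), BaraA1 (3.20 ± 0.20) and Dso1 (2.15 ± 0.14) had the smallest p. For the 34 Toll and Imd pathway genes, 19 rose, 0 fell and 15 did not pass (25 and 0 adjusted over the list alone, camera adjusted p = 1.1e-08, adjusted p = 0.114 with an estimated correlation). PGRP-SB1 (4.11 ± 0.34), PGRP-SD (2.88 ± 0.25) and PGRP-LF (1.99 ± 0.21) and the NF-kappaB gene Rel (0.97 ± 0.11) rose. Of the 51 glutathione transferase and P450 genes, 29 rose, 1 fell and 21 did not pass (31 and 1 adjusted over the list alone, camera adjusted p = 3.93e-12, adjusted p = 0.304 with an estimated correlation). Cyp309a1 (2.05 ± 0.21), Cyp6d2 (3.06 ± 0.31), Cyp4e2 (2.11 ± 0.25) and Cyp6a8 (4.14 ± 0.49) rose and Cyp4e3 fell. Among 22 genes of reactive oxygen species handling, 7 rose and 1 fell while 14 did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 0.00148, adjusted p = 0.444 with an estimated correlation). Irc (1.41 ± 0.17), Prx2 (0.92 ± 0.16), cnc (0.59 ± 0.10) and Prx4 (1.17 ± 0.24) rose and the NADPH oxidase gene Duox fell. 8 of the 22 heat shock protein genes rose, 2 fell and 12 did not pass (8 and 2 adjusted over the list alone, camera adjusted p = 0.00458, adjusted p = 0.304 with an estimated correlation). Hsp68 (1.22 ± 0.13), Hsp83 (0.96 ± 0.11), Hsp70Ab (3.16 ± 0.47) and Hsp70Aa (2.66 ± 0.43) rose, while Hsp67Ba and Hsp67Bc fell. Of the 18 fat body genes, 9 rose, 0 fell and 9 did not pass (12 and 0 adjusted over the list alone, camera adjusted p = 5.38e-05, adjusted p = 0.304 with an estimated correlation). Lsp1alpha (6.18 ± 0.36), Lst (3.13 ± 0.20), fon (1.76 ± 0.17) and Tsf1 (2.37 ± 0.23) rose, and the summed fat body list was 25249 and 21272 CPM at day 40 against 8865 and 12550.1 at day 3. Among 32 lipid metabolism genes, 16 rose and 0 fell while 16 did not pass (20 and 0 adjusted over the list alone, camera adjusted p = 2.17e-08, adjusted p = 0.304 with an estimated correlation). bmm (1.91 ± 0.14), Lsd-2 (1.24 ± 0.13), Mtp (1.38 ± 0.15) and Npc2b (1.22 ± 0.14) rose. For the 81 cytosolic ribosomal protein genes, 63 rose, 0 fell and 18 did not pass (69 and 0 adjusted over the list alone, camera adjusted p = 1.97e-24, adjusted p = 0.304 with an estimated correlation). RpL35 (1.22 ± 0.11), RpL18 (1.098 ± 0.11), RpL35A (1.18 ± 0.12) and RpS26 (1.34 ± 0.14) rose. Pdf rose (0.56 ± 0.16, adjusted p = 0.0413) and was the core clock member that passed, while Orco (-0.68 ± 0.30, adjusted p = 0.133) did not pass, nor did its interaction with genotype (0.63 ± 0.40, adjusted p = 0.641).

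Lists called lower with age in orco2 heads were those of phototransduction, muscle, neurons, mitochondria and cuticle. Of the 33 phototransduction genes, 5 rose, 13 fell and 15 did not pass (7 and 13 adjusted over the list alone, camera adjusted p = 0.0116, adjusted p = 0.304 with an estimated correlation). eys (-1.46 ± 0.10), retinin (-2.05 ± 0.18), rdgA (-1.253 ± 0.14) and Cpn (-0.74 ± 0.10) fell, retinin encoding a corneal lens protein, while pinta, ninaE, Rh3, Rh4 and Rh5 rose. Among 24 muscle genes, 0 rose and 16 fell while 8 did not pass (0 and 19 adjusted over the list alone, camera adjusted p = 6.83e-12, adjusted p = 0.304 with an estimated correlation). Mlc2 (-1.495 ± 0.10), Mlc1 (-1.20 ± 0.10), Strn-Mlck (-1.01 ± 0.11) and up (-1.18 ± 0.13) fell. 0 of the 20 neuron and synapse genes rose, 17 fell and 3 did not pass (0 and 19 adjusted over the list alone, camera adjusted p = 7.18e-11, adjusted p = 0.304 with an estimated correlation). Gad1 (-1.49 ± 0.10), ChAT (-1.09 ± 0.16), Snap25 (-0.83 ± 0.12) and Syt1 (-1.11 ± 0.16) fell. For the 65 oxidative phosphorylation genes, 0 rose, 26 fell and 39 did not pass (0 and 29 adjusted over the list alone, camera adjusted p = 8.85e-11, adjusted p = 0.367 with an estimated correlation). ATPsynC (-0.88 ± 0.09), UQCR-6.4 (-0.97 ± 0.13), blw (-0.85 ± 0.12) and ATPsynbeta (-0.80 ± 0.11) had the smallest p. Of the 28 adult cuticle protein genes, 1 rose, 11 fell and 16 did not pass (1 and 13 adjusted over the list alone, camera adjusted p = 0.000183, adjusted p = 0.114 with an estimated correlation). Vajk2 (-4.19 ± 0.20), Vajk3 (-4.42 ± 0.38), Cpr49Ae (-1.73 ± 0.19) and Cpr62Bb (-1.03 ± 0.15) fell and Cpr51A rose. Among 36 odorant binding and olfactory support genes, 7 rose and 0 fell while 29 did not pass (7 and 0 adjusted over the list alone, camera adjusted p = 0.00119, adjusted p = 0.48 with an estimated correlation). a10 (5.93 ± 0.40), Obp56a (3.08 ± 0.31), lush (1.63 ± 0.33) and Obp99a (3.40 ± 0.69) rose. Among single genes, CAH5 was at least 321-fold higher at day 40, and SPH93 (6.86 ± 0.37), CG3117 (6.50 ± 0.87) and Srg3 (5.11 ± 0.39) rose. CG11458 was at least 213-fold lower, and CG7214 (-8.55 ± 0.36), Acp1 (-7.06 ± 0.61), CG34327 (-6.37 ± 0.75) and CG31904 (-5.92 ± 0.23) fell. CG12374 fell to 0 from 33.3 CPM in day 3 replicate 1 (which held alphaTry) and 0.224 in replicate 2. Camera called 14 of 32 lists, 9 higher and 5 lower, and 0 with an estimated correlation (smallest p = 0.114). Without day 40 replicate 1 or 2 the count of changed genes was 771 or 1407, and without day 3 replicate 2 it was 4500.

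Whether age changed the heads differently in orco2 was tested as an interaction. 1418 genes changed with age the same way in both genotypes, 751 higher and 667 lower, against 134 and 101 by chance. 3 genes changed in opposite directions, namely CG4962, phtm and Cyp4e3, against 233 by chance. In the interaction test 1 of 12243 genes passed, the P450 gene Cyp4e3 (-2.69 ± 0.18, adjusted p = 0.00529 by edgeR), which rose with age in w1118 (1.76 ± 0.13) and fell in orco2 (-0.93 ± 0.12). At an unadjusted p under 0.05 there were 1215 genes, and DESeq2 called 159 and limma-voom 1. Of the 36 odorant binding and olfactory support genes, 0 rose, 0 fell and 36 did not pass (2 and 1 adjusted over the list alone, camera adjusted p = 0.0109, adjusted p = 0.723 with an estimated correlation). Among 33 phototransduction genes, 0 rose and 0 fell while 33 did not pass (1 and 5 adjusted over the list alone, camera adjusted p = 7.4e-05, adjusted p = 0.723 with an estimated correlation). 0 of the 22 heat shock protein genes rose, 0 fell and 22 did not pass (1 and 0 adjusted over the list alone, camera adjusted p = 0.0234, adjusted p = 0.723 with an estimated correlation). For the 51 glutathione transferase and P450 genes, 0 rose, 1 fell and 50 did not pass (1 and 2 adjusted over the list alone, camera adjusted p = 0.00205, adjusted p = 0.723 with an estimated correlation). Of the 65 oxidative phosphorylation genes, 0 rose, 0 fell and 65 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 3.31e-10, adjusted p = 0.723 with an estimated correlation). Among 81 cytosolic ribosomal protein genes, 0 rose and 0 fell while 81 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.00351, adjusted p = 0.723 with an estimated correlation). 0 of the 32 lipid metabolism genes rose, 0 fell and 32 did not pass (2 and 0 adjusted over the list alone, camera adjusted p = 0.0234, adjusted p = 0.723 with an estimated correlation). For the 20 neuron and synapse genes, 0 rose, 0 fell and 20 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.00406, adjusted p = 0.723 with an estimated correlation). Here rose means a more positive change with age in orco2 than in w1118, and the phototransduction and neuron lists were called lower while the other 6 were called higher. Camera called 8 of 32 lists, 6 higher and 2 lower, and 0 with an estimated correlation (smallest p = 0.723). Without w1118 day 3 replicate 1 or 2 the interaction count was 0 or 0, without orco2 day 3 replicate 1 or 2 it was 286 or 408, and without orco2 day 40 replicate 1 or 2 it was 2 or 0. The count of lists was 2 without orco2 day 3 replicate 1 and 13 without replicate 2.

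**Figure D2:**
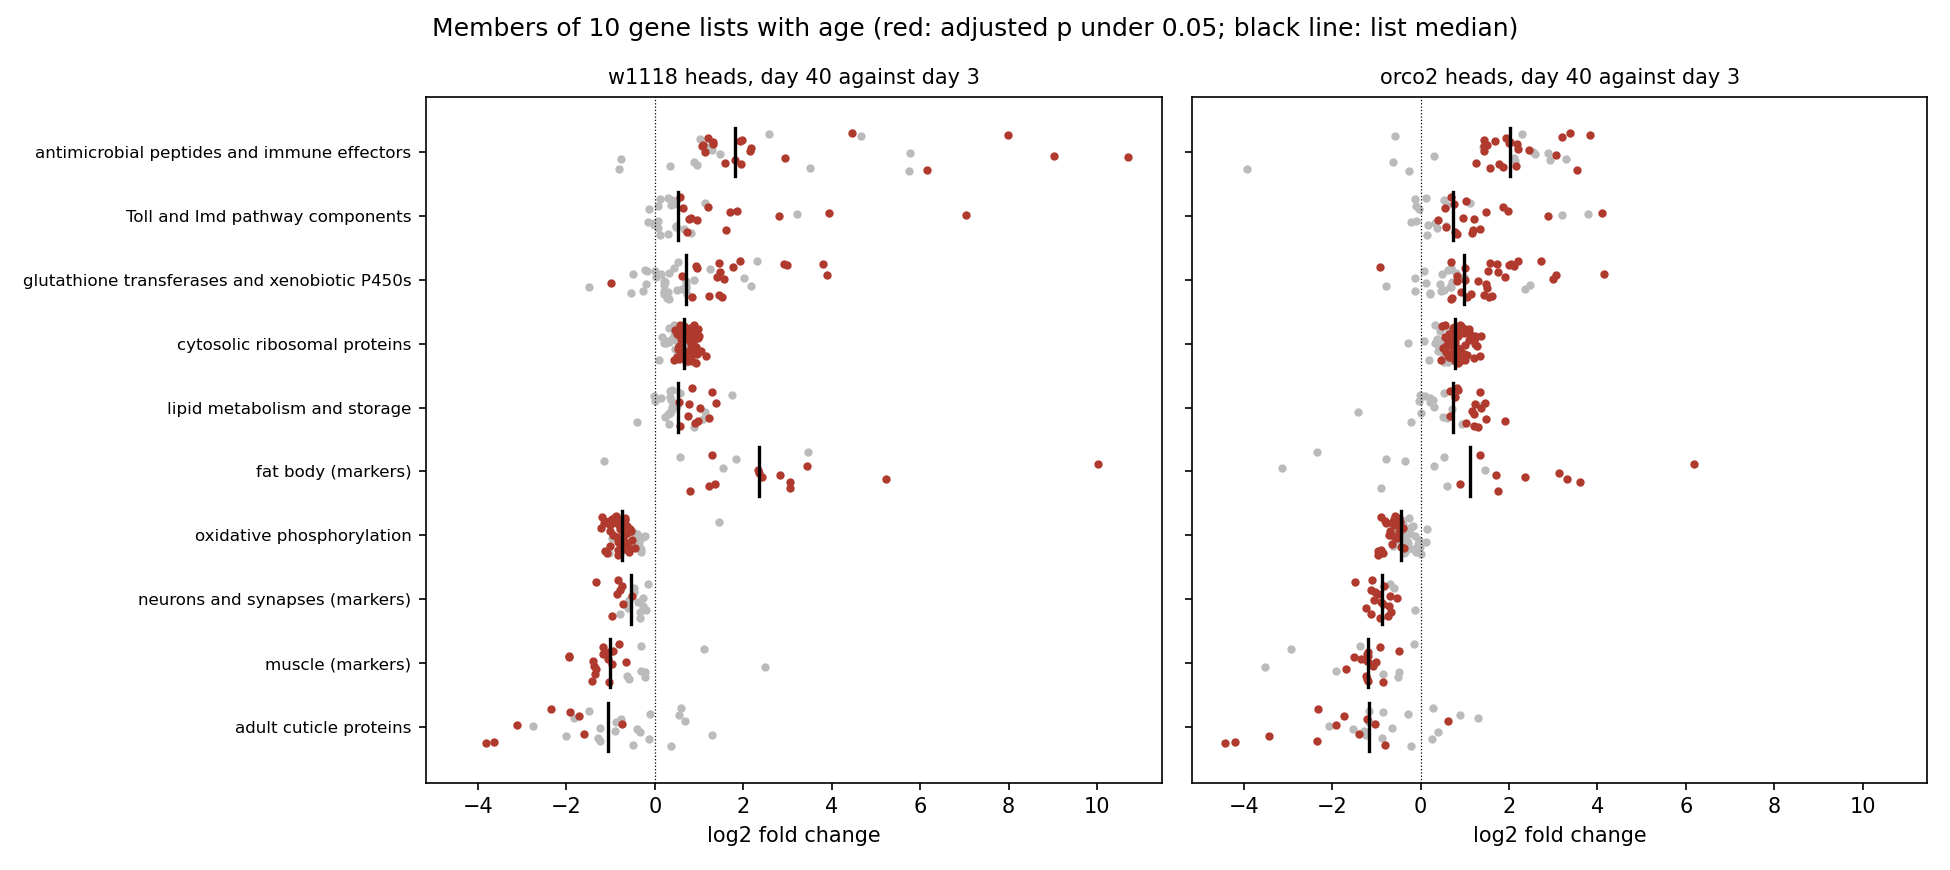
Log2 fold change from day 3 to day 40 (x axis) of the members of 10 gene lists in w1118 heads (left) and orco2 heads (right), each point a gene, red when its adjusted p was under 0.05, black lines the medians of the genes drawn, and genes without counts in 1 of the compared groups left out. In w1118, 16 muscle and 45 oxidative phosphorylation genes fell while 59 ribosomal protein genes rose.

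**Figure D3:**
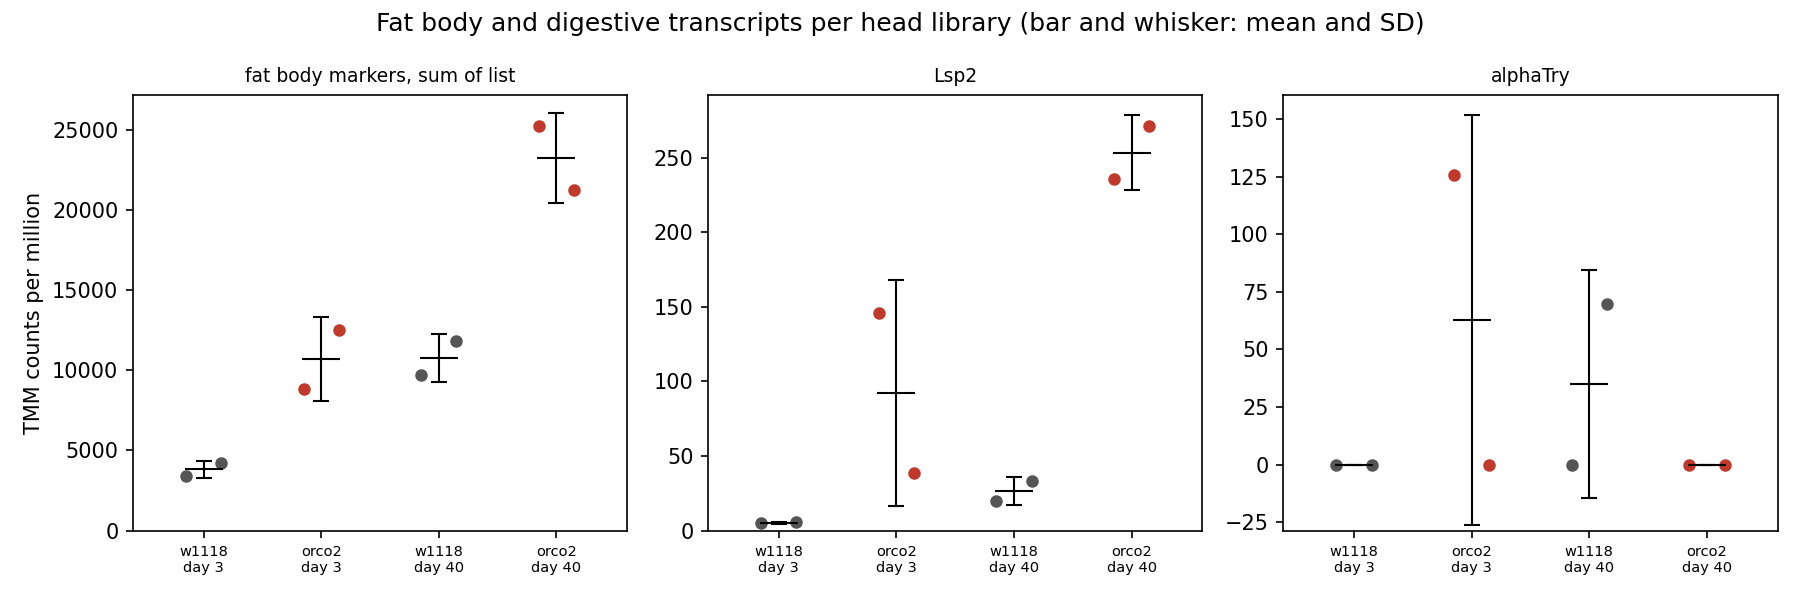
Summed fat body list, Lsp2 and alphaTry (CPM, y axis) in each of the 8 head libraries by group, each point a library, with bar and whisker the mean ± SD. alphaTry was 126 CPM in day 3 orco2 replicate 1 and 69.8 CPM in day 40 w1118 replicate 2, and 0 in the other 6.

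The guts of old orco2 flies were compared with those of w1118 (day 40, 3 libraries against 3). 3573 of 13453 tested genes changed, 1544 of them higher and 2029 lower, 3003 of them by at least 2-fold. With testis and accessory gland levels as covariates (added after the data were seen) 0 genes changed by edgeR, with 2193 at an unadjusted p under 0.05. The majority turned with the DESeq2 Wald test, which called 3552 higher and 3002 lower. 9 core clock genes fell in orco2, including per (9.54 ± 1.44 against 56.3 ± 25.1 CPM, -2.56 ± 0.37, adjusted p = 0.00524), tim (-2.15 ± 0.28, adjusted p = 0.00392), vri (-2.35 ± 0.33, adjusted p = 0.00455) and cwo (-1.76 ± 0.26, adjusted p = 0.00547). Pdp1 (-1.63 ± 0.31), Pdfr (-1.22 ± 0.26), jet (-1.08 ± 0.31), Clk (-1.03 ± 0.26) and cyc (-0.70 ± 0.21) were the other 5. Of the 16 core clock genes, 0 rose, 9 fell and 7 did not pass (1 and 13 adjusted over the list alone, camera adjusted p = 0.000135, adjusted p = 0.704 with an estimated correlation). Among 53 digestive enzyme genes, 13 rose and 1 fell while 39 did not pass (13 and 1 adjusted over the list alone, camera adjusted p = 0.000138, adjusted p = 0.727 with an estimated correlation). The serine protease genes Jon99Fi (5.15 ± 0.62), Jon25Bii (4.16 ± 0.62), Jon65Aii (3.26 ± 0.58) and Jon25Bi (3.80 ± 0.70) rose, whereas tobi fell (-8.15 ± 0.64). The lysozyme gene LysC was at least 1676-fold higher and LysD rose (10.98 ± 0.97), although reads of the near-identical Lys copies may be shared. 3 of the 35 Toll and Imd pathway genes rose, 19 fell and 13 did not pass (3 and 21 adjusted over the list alone, camera adjusted p = 6.02e-05, adjusted p = 0.704 with an estimated correlation). The NF-kappaB genes dl (-1.94 ± 0.23) and Dif (-1.42 ± 0.23), Tak1 (-1.24 ± 0.22) and cact (-1.21 ± 0.21) fell, while PGRP-SC1a, PGRP-SC1b and PGRP-SC2 rose. For the 19 intestinal stem cell and enteroblast genes, 0 rose, 8 fell and 11 did not pass (0 and 9 adjusted over the list alone, camera adjusted p = 0.000196, adjusted p = 0.704 with an estimated correlation). Egfr (-1.44 ± 0.19), its ligand gene spi (-0.91 ± 0.20), the Notch target E(spl)mbeta-HLH (-2.89 ± 0.45) and cic (-1.87 ± 0.40) fell. Of the 22 enterocyte and septate junction genes, 0 rose, 4 fell and 18 did not pass (0 and 4 adjusted over the list alone, camera adjusted p = 0.00037, adjusted p = 0.704 with an estimated correlation). cora (-1.98 ± 0.26), dlg1 (-1.40 ± 0.20), scrib (-1.40 ± 0.22) and Myo31DF (-1.63 ± 0.31) were the 4 that fell. Among 21 peritrophic matrix and chitin genes, 0 rose and 7 fell while 14 did not pass (0 and 9 adjusted over the list alone, camera adjusted p = 0.0377, adjusted p = 0.704 with an estimated correlation). obst-E (-2.47 ± 0.37), Muc68Ca (-3.35 ± 0.52), Cht9 (-4.22 ± 0.79) and Cht4 (-2.81 ± 0.57) fell. 0 of the 17 insulin and adipokinetic signalling genes rose, 8 fell and 9 did not pass (1 and 10 adjusted over the list alone, camera adjusted p = 0.00151, adjusted p = 0.704 with an estimated correlation). Pi3K92E (-1.66 ± 0.21), ImpL2 (-2.72 ± 0.40) and InR (-1.18 ± 0.20) fell, and tobi belongs to this list and to the digestive list. For the 33 lipid metabolism genes, 2 rose, 8 fell and 23 did not pass (2 and 8 adjusted over the list alone, camera adjusted p = 0.0388, adjusted p = 0.764 with an estimated correlation). sug (-2.80 ± 0.42), Hsl (-1.23 ± 0.24), Hnf4 (-1.13 ± 0.23) and Mondo (-1.37 ± 0.28) fell, while Npc2d and Desat1 rose.

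In the orco2 guts the muscle, neuronal and heat shock lists were called lower and those of the reproductive tract higher. 0 of the 23 muscle genes rose, 11 fell and 12 did not pass (0 and 13 adjusted over the list alone, camera adjusted p = 0.000138, adjusted p = 0.704 with an estimated correlation). The sarcomere genes Obsc (-3.20 ± 0.41), bt (-2.39 ± 0.32), Mhc (-1.95 ± 0.27) and sls (-2.76 ± 0.39) fell. Of the 20 neuron and synapse genes, 0 rose, 8 fell and 12 did not pass (0 and 13 adjusted over the list alone, camera adjusted p = 0.000398, adjusted p = 0.704 with an estimated correlation). Syx1A (-1.92 ± 0.36), unc-13 (-1.16 ± 0.27), Syn (-2.63 ± 0.66) and Vmat (-3.02 ± 0.76) fell. Among 14 glia genes, 1 rose and 4 fell while 9 did not pass (2 and 6 adjusted over the list alone, camera adjusted p = 0.0388, adjusted p = 0.704 with an estimated correlation). loco (-1.49 ± 0.23), bnb (-1.96 ± 0.34), Tret1-1 (-1.13 ± 0.28) and Gs2 (-1.41 ± 0.38) fell and Gat rose. For the 23 heat shock protein genes, 1 rose, 14 fell and 8 did not pass (1 and 16 adjusted over the list alone, camera adjusted p = 6.02e-05, adjusted p = 0.704 with an estimated correlation). The co-chaperone gene stv (-3.73 ± 0.40) and Hsp70Aa (-7.91 ± 1.38), Hsp70Bb (-7.43 ± 0.93), Hsp70Bbb (-6.99 ± 0.86) and Hsp70Bc (-7.91 ± 1.01) fell and CG4456 rose. Hsp70Aa stood at 85.3, 41.3 and 38.1 CPM in the w1118 guts and 0.166, 0.203 and 0.306 in the orco2 guts. 20 of the 38 accessory gland and ejaculatory duct genes rose, 0 fell and 18 did not pass (26 and 1 adjusted over the list alone, camera adjusted p = 0.000111, adjusted p = 0.727 with an estimated correlation). Acp63F (6.99 ± 1.37), Sfp65A (7.46 ± 1.504) and Sfp26Ad (6.72 ± 1.44) and the sex peptide gene SP (6.55 ± 1.32) rose, as did Sfp70A4 (8.47 ± 1.31) outside the list. The summed accessory gland list was 11640.2, 15885 and 13990.3 CPM in orco2 and 1619, 6335 and 4081 CPM in w1118. Of the 28 testis and sperm genes, 6 rose, 0 fell and 22 did not pass (6 and 0 adjusted over the list alone, camera adjusted p = 6.02e-05, adjusted p = 0.727 with an estimated correlation). Mst84Db (2.89 ± 0.71), Mst77F (2.98 ± 0.75), sa (2.59 ± 0.72) and fzo (2.85 ± 0.81) rose, Mst77F encoding a sperm chromatin protein, and the summed testis list was 7239.9, 12625 and 9981 CPM against 1555, 4213 and 1081 CPM. Among 34 cell proliferation genes, 4 rose and 2 fell while 28 did not pass (2 and 2 adjusted over the list alone, camera adjusted p = 0.0377, adjusted p = 0.727 with an estimated correlation). Cdk1 (2.97 ± 0.61), CycB (2.41 ± 0.63), pim (2.66 ± 0.77) and tum (1.28 ± 0.39) rose beside those testis genes, while Dp and E2f1 fell. 0 of the 81 cytosolic ribosomal protein genes rose, 4 fell and 77 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.000138, adjusted p = 0.764 with an estimated correlation). RpL3 (-1.253 ± 0.31), RpS6 (-1.07 ± 0.30), RpL17 (-1.18 ± 0.36) and RpL7 (-1.03 ± 0.32) were the 4 that fell, and with the covariates the ribosomal and lipid medians became positive (0.19 and 0.35). Among single genes, CG43145 (8.85 ± 1.45), Spn28Db (8.84 ± 1.57) and lncRNA:CR44311 (8.24 ± 1.53) rose, and CG1304 (-7.71 ± 0.90) and CG8642 (-7.67 ± 1.35) fell. For the 13 Turandot and JAK-STAT genes, 1 rose, 5 fell and 7 did not pass (1 and 7 adjusted over the list alone, camera adjusted p = 0.118, adjusted p = 0.704 with an estimated correlation). TotM rose, and upd2, upd3, Socs36E, hop and dome fell. Camera called 16 of 32 lists, 4 higher and 12 lower, and 0 with an estimated correlation (smallest p = 0.704). Without w1118 replicate 3 the count of changed genes was 1818, and without orco2 replicate 1, 2 or 3 it was 1340, 862 or 590. The orco2 replicate 3 lay between replicates 1 and 2 in 99.3% of the genes that differed at least 2-fold between them. The w1118 replicate 2 gut held the photoreceptor transcript ninaE at 45.3 CPM.

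The guts of per01 flies were compared with those of w1118 at day 40 (3 libraries against 3). 2554 of 13453 tested genes changed, 1299 of them higher and 1255 lower, 2143 of them by at least 2-fold, and 109 changed with those covariates. The balance of directions was not stable, with 1201 higher and 1487 lower by DESeq2 size factors and 1998 higher and 2387 lower by the DESeq2 Wald test. The transcript of per itself did not pass (31.1 ± 7.28 against 56.3 ± 25.1 CPM, -0.85 ± 0.36, adjusted p = 0.129). tim rose (1.47 ± 0.28, adjusted p = 0.0118) and CkIIalpha rose (0.84 ± 0.20), whereas Clk (-2.19 ± 0.27, adjusted p = 0.00363), the cryptochrome gene cry (-1.95 ± 0.25, adjusted p = 0.00389), Pdfr (-1.16 ± 0.26) and sgg (-0.89 ± 0.25) fell. Of the 53 digestive enzyme genes, 37 rose, 0 fell and 16 did not pass (40 and 0 adjusted over the list alone, camera adjusted p = 3.42e-25, adjusted p = 0.874 with an estimated correlation). Jon99Cii (5.27 ± 0.58), Jon99Ciii (4.39 ± 0.50), Jon99Fi (5.49 ± 0.63) and tobi (4.63 ± 0.54) rose, and the summed digestive list was 184097, 260932 and 329843 CPM in per01 against 43186, 17077 and 17680 CPM in w1118. LysC was at least 86291-fold higher, and LysD (12.14 ± 1.01) and LysB (10.001 ± 0.84) rose while LysX fell (-6.76 ± 1.07). 19 of the 66 oxidative phosphorylation genes rose, 0 fell and 47 did not pass (21 and 0 adjusted over the list alone, camera adjusted p = 6.51e-09, adjusted p = 0.874 with an estimated correlation). ND-AGGG (2.62 ± 0.30), ND-15 (1.78 ± 0.28), UQCR-11 (1.90 ± 0.30) and ND-MLRQ (2.17 ± 0.35) rose. Among 53 glutathione transferase and P450 genes, 12 rose and 3 fell while 38 did not pass (16 and 4 adjusted over the list alone, camera adjusted p = 0.000217, adjusted p = 0.874 with an estimated correlation). Cyp12d1-p (3.17 ± 0.37), Cyp4d1 (4.39 ± 0.53), Cyp28d1 (3.21 ± 0.39) and Cyp4p1 (2.55 ± 0.32) rose, while Cyp6a14, Cyp6a17 and GstE1 fell. For the 81 cytosolic ribosomal protein genes, 4 rose, 0 fell and 77 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.0186, adjusted p = 0.939 with an estimated correlation). RpL38 (2.04 ± 0.51), RpS9 (0.86 ± 0.23), RpL39 (1.33 ± 0.37) and RpL29 (1.21 ± 0.35) were the 4 that rose. Of the 19 enteroendocrine genes, 5 rose, 2 fell and 12 did not pass (6 and 2 adjusted over the list alone, camera adjusted p = 0.0484, adjusted p = 0.874 with an estimated correlation). The gut hormone genes CCHa2 (3.35 ± 0.65), NPF (3.09 ± 0.69) and Orcokinin (2.65 ± 0.62) and the prohormone convertase gene amon (1.96 ± 0.48) rose, while Cadps and Pdfr fell. Among 38 accessory gland and ejaculatory duct genes, 17 rose and 0 fell while 21 did not pass (25 and 1 adjusted over the list alone, camera adjusted p = 2.51e-06, adjusted p = 0.874 with an estimated correlation). Acp63F (7.14 ± 1.38), Sfp65A (7.45 ± 1.504), SP (6.46 ± 1.32) and Sfp26Ad (6.77 ± 1.44) rose, and the summed list was 16023, 26528 and 2037 CPM in the 3 per01 libraries.

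The immune signalling, heat shock and neuronal lists were called lower in the per01 guts. 3 of the 35 Toll and Imd pathway genes rose, 7 fell and 25 did not pass (4 and 10 adjusted over the list alone, camera adjusted p = 0.0286, adjusted p = 0.874 with an estimated correlation). PGRP-LC (-1.71 ± 0.30), dl (-1.27 ± 0.23), Tl (-1.65 ± 0.31) and Dif (-1.17 ± 0.23) fell, while PGRP-SC1a, PGRP-SC1b and PGRP-SC2 rose. Of the 13 Turandot and JAK-STAT genes, 0 rose, 3 fell and 10 did not pass (0 and 6 adjusted over the list alone, camera adjusted p = 0.0132, adjusted p = 0.874 with an estimated correlation). The cytokine gene upd3 (-3.65 ± 0.61), Socs36E (-2.41 ± 0.26) and hop (-0.83 ± 0.24) were the 3 that fell. Among 23 heat shock protein genes, 0 rose and 13 fell while 10 did not pass (0 and 14 adjusted over the list alone, camera adjusted p = 1.36e-06, adjusted p = 0.874 with an estimated correlation). stv (-2.59 ± 0.38), Hsp70Bc (-5.81 ± 0.92), Hsp70Bb (-5.01 ± 0.83) and Hsp70Ba (-5.70 ± 0.96) fell, and Hsp70Aa stood at 1.35, 0 and 4.01 CPM in per01 against 85.3, 41.3 and 38.1 in w1118. For the 20 neuron and synapse genes, 0 rose, 4 fell and 16 did not pass (0 and 5 adjusted over the list alone, camera adjusted p = 0.00979, adjusted p = 0.874 with an estimated correlation). unc-13 (-1.36 ± 0.28), Syx1A (-1.47 ± 0.35), nSyb (-2.28 ± 0.59) and Rim (-1.59 ± 0.44) were the 4 that fell. Among single genes, mthl8 was at least 977-fold lower, CG8642 was 651-fold lower (exact 95% interval 179.9 to 5376) and CG43235 was 443-fold lower (exact 95% interval 122 to 3664), while CG5070 (-10.33 ± 1.254) and the alcohol dehydrogenase gene Adh (-7.40 ± 0.77) fell. CG44406 was 1519-fold higher (exact 95% interval 272 to 60047), with 11.3, 32.03 and 0.186 CPM in per01 replicates 1 to 3, the first 2 of which held accessory gland transcripts. CG43145 (8.24 ± 1.42) and Spn28Db (8.23 ± 1.54) rose. Camera called 10 of 32 lists, 6 higher and 4 lower, and 0 with an estimated correlation (smallest p = 0.874). The medians of the odorant receptor and lipid lists, neither of them called, were positive and became negative with DESeq2 size factors. Without w1118 replicate 2 or 3 the count of changed genes was 973 or 1115, and without per01 replicate 2 it was 1076.

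The mutants were set against each other in the gut (per01 against orco2 at day 40, 3 libraries against 3). 726 of 13453 tested genes changed, 448 of them higher and 278 lower, 688 of them by at least 2-fold, and 9 changed with the covariates. tim (3.62 ± 0.30, adjusted p = 0.0025), vri (3.12 ± 0.34, adjusted p = 0.00595), Pdp1 (1.78 ± 0.31), per (1.71 ± 0.36, adjusted p = 0.0398) and cwo (1.26 ± 0.26) rose, and Clk (-1.16 ± 0.26) and cry (-1.27 ± 0.24) fell. Among 16 core clock genes, 5 rose and 2 fell while 9 did not pass (6 and 2 adjusted over the list alone, camera adjusted p = 0.0149, adjusted p = 0.529 with an estimated correlation). 19 of the 53 digestive enzyme genes rose, 0 fell and 34 did not pass (31 and 0 adjusted over the list alone, camera adjusted p = 4.33e-11, adjusted p = 0.529 with an estimated correlation). tobi (12.78 ± 0.76), betaTry (3.19 ± 0.52), Jon99Ciii (2.60 ± 0.46) and Jon65Aiv (2.34 ± 0.42) rose. Of the 53 glutathione transferase and P450 genes, 10 rose, 2 fell and 41 did not pass (20 and 7 adjusted over the list alone, camera adjusted p = 0.0015, adjusted p = 0.529 with an estimated correlation). Cyp12d1-p (2.14 ± 0.36), Cyp6a14 (1.55 ± 0.26), Cyp6a20 (2.15 ± 0.36) and Cyp6a23 (2.69 ± 0.46) rose, while Cyp309a2 and GstE1 fell. Among 22 genes of reactive oxygen species handling, 4 rose and 1 fell while 17 did not pass (8 and 2 adjusted over the list alone, camera adjusted p = 0.00641, adjusted p = 0.529 with an estimated correlation). Nox (2.27 ± 0.44), Keap1 (1.32 ± 0.29), Gclc (1.44 ± 0.33) and Prx2 (1.42 ± 0.33) rose and GstO1 fell. For the 19 enteroendocrine genes, 2 rose, 0 fell and 17 did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 0.000805, adjusted p = 0.529 with an estimated correlation). IA-2 (1.92 ± 0.40) and amon (2.31 ± 0.49) rose. Of the 22 enterocyte and septate junction genes, 2 rose, 0 fell and 20 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.0015, adjusted p = 0.529 with an estimated correlation). Vha100-4 (1.81 ± 0.36) and Myo31DF (1.40 ± 0.31) rose. 2 of the 33 lipid metabolism genes rose, 0 fell and 31 did not pass (10 and 0 adjusted over the list alone, camera adjusted p = 0.000884, adjusted p = 0.529 with an estimated correlation). sug (2.16 ± 0.41) and whd (1.80 ± 0.34) rose. Among 23 muscle genes, 2 rose and 0 fell while 21 did not pass (11 and 0 adjusted over the list alone, camera adjusted p = 0.000665, adjusted p = 0.529 with an estimated correlation). Mlc2 (1.19 ± 0.25) and wupA (1.16 ± 0.26) rose.

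Further lists differed between the mutant guts as sets, with few members passing alone. Of the 35 Toll and Imd pathway genes, 1 rose, 0 fell and 34 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.00415, adjusted p = 0.542 with an estimated correlation). That member was cact (0.88 ± 0.21). Among 81 cytosolic ribosomal protein genes, 1 rose and 0 fell while 80 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 2.53e-11, adjusted p = 0.529 with an estimated correlation). RpS14a rose (1.42 ± 0.29). 1 of the 34 cell proliferation genes rose, 2 fell and 31 did not pass (2 and 13 adjusted over the list alone, camera adjusted p = 0.00168, adjusted p = 0.529 with an estimated correlation). CycE (-2.41 ± 0.49) and Klp61F (-1.61 ± 0.33) fell and tum rose. For the 19 intestinal stem cell and enteroblast genes, 0 rose, 0 fell and 19 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.0212, adjusted p = 0.529 with an estimated correlation). Of the 66 oxidative phosphorylation genes, 0 rose, 0 fell and 66 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 4.64e-09, adjusted p = 0.529 with an estimated correlation). 0 of the 28 testis and sperm genes rose, 0 fell and 28 did not pass (0 and 21 adjusted over the list alone, camera adjusted p = 1.39e-07, adjusted p = 0.529 with an estimated correlation). The summed testis list was 4665, 874 and 803 CPM in per01 and 7239.9, 12625 and 9981 CPM in orco2. As sets the proliferation and testis lists were called lower in per01, and the stem cell and oxidative phosphorylation lists higher. Among single genes, CG3397 was at least 524-fold higher and CG1304 (10.57 ± 1.002), CG9988 (8.73 ± 1.29), lncRNA:CR43808 (7.86 ± 1.52) and CG33346 (7.62 ± 0.62) rose. CG30429 was at least 1436-fold lower, CG32379 at least 1098-fold lower, mthl8 at least 334-fold lower and lncRNA:CR44534 at least 296-fold lower, CG43235 was 432-fold lower (exact 95% interval 119 to 3567) and CG13675 fell (-8.77 ± 1.5001). Camera called 14 of 32 lists, 12 higher and 2 lower, and 0 with an estimated correlation (smallest p = 0.529). The accessory gland list, not called, had a median of 0.04 that became negative with DESeq2 size factors. Without orco2 replicate 1, 2 or 3 the count of changed genes was 30, 19 or 20, and without per01 replicate 1, 2 or 3 it was 5211, 79 or 88. The majority turned to lower with DESeq2 (1739 higher and 2776 lower) and without per01 replicate 1 (2325 higher and 2886 lower) or replicates 1 and 2 (1680 higher and 2023 lower), and with the covariates the Toll and Imd and ribosomal medians became negative.

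Genes that changed in both mutant guts were counted last. 1445 genes changed the same way in orco2 and per01, 538 higher and 907 lower, against 149 and 189 by chance, and 23 changed in opposite directions against 339.95. Both comparisons used the same 3 w1118 libraries, so their fold changes correlated at 0.499 in 20 simulations of unchanged groups, against 0.604 observed across genes, which are not independent replicates. The covariance was 1.96, against 0.273 (range 0.244 to 0.291) and 0 shared calls simulated. Shared controls or accessory gland RNA may add to the overlap. LysC, LysD, CG43145, Spn28Db and the accessory gland genes Acp63F and SP rose in both mutants, and stv, Hsp70Bc, dl, Dif, upd3 and CG8642 fell in both. With the covariates, where edgeR called 0 genes in orco2, the overlap was empty. In orco2, 325 genes changed the same way in heads and guts at day 40, 113 higher and 212 lower of 10445 genes tested in both, against 77.9 and 97.5 by chance, but at a log2 fold of at least 1 more were higher (80) than lower (42). Another 100 changed in opposite directions against 215 by chance. The clock genes per, tim, vri, cwo and Pdp1 fell in both tissues.

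**Figure D4:**
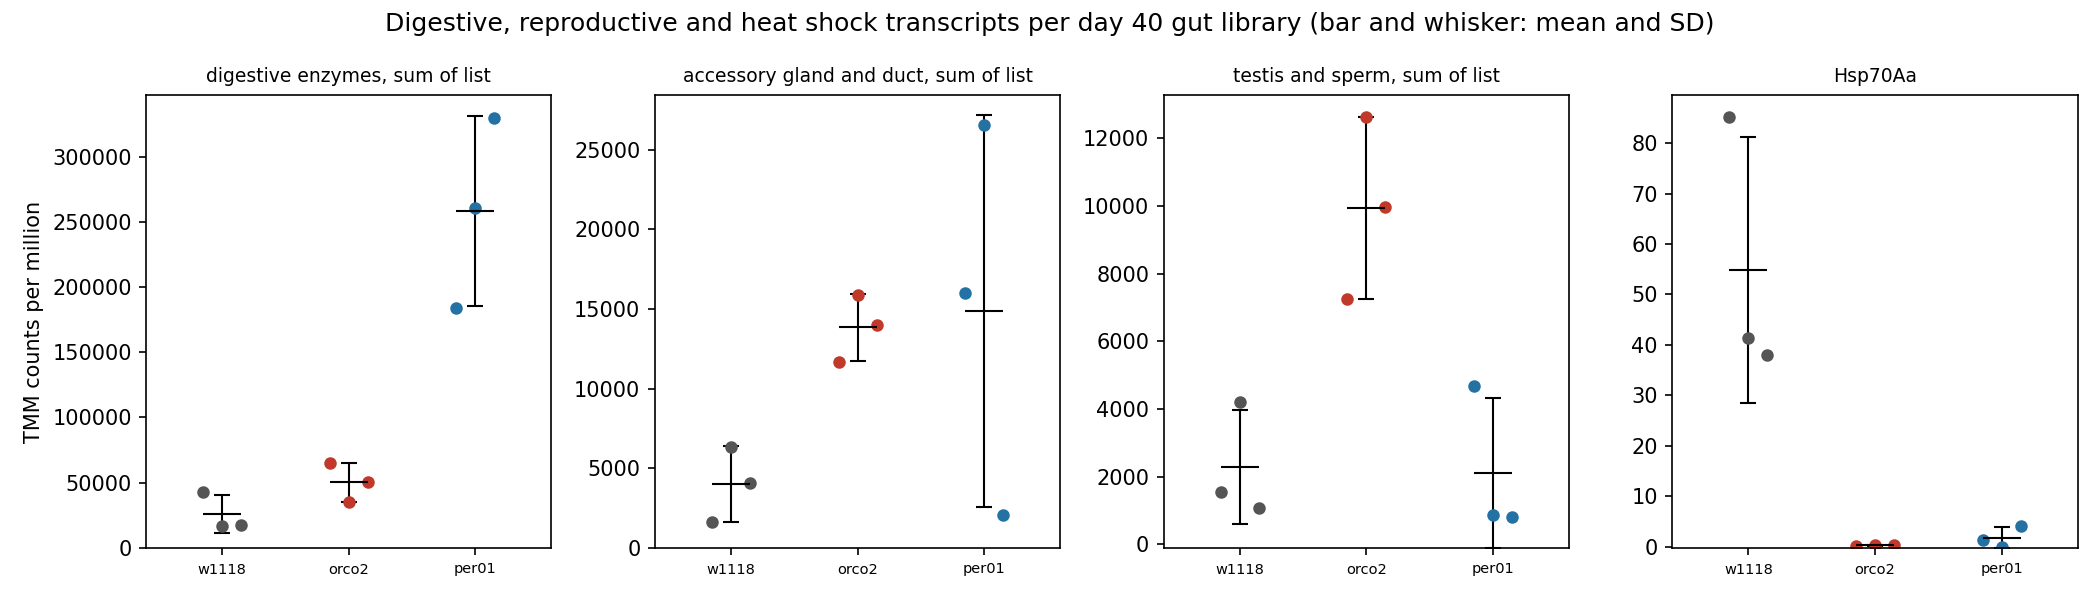
Summed digestive, accessory gland and testis lists and Hsp70Aa (CPM, y axis) in each of the 9 gut libraries by group, each point a library, with bar and whisker the mean ± SD. The accessory gland sum was 2037 CPM in per01 replicate 3, against 16023 and 26528 CPM in replicates 1 and 2.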

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

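The age by genotype interaction in heads was planned, and the test without 2 head libraries was chosen after the result was seen. Cyp4e3 changed with age differently in the genotypes, with an interaction of -2.69 on the log2 scale. 8 gene lists differed as sets in the same test, with more positive changes with age in orco2 for odorant binding (median 0.58), heat shock (0.15), glutathione transferases and P450s (0.36), oxidative phosphorylation (0.25), ribosomal proteins (0.12) and lipid metabolism (0.16). More negative changes were measured for phototransduction (-0.33) and neuron and synapse genes (-0.29). None of the 8 lists was called with an estimated correlation or by fry. The test without the 2 head libraries that held alphaTry rested on lone libraries. No explanation of these differences was tested.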

How the results depend on the processing

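Tests with the covariates, without the 2 head libraries and without the 2 per01 libraries were chosen after the data were seen, and the others before. Named genes gave 4727 values under alternatives, of which 3877 kept direction and call, 834 no longer passed, 14 newly passed and 2 reversed. Lists gave 920 values, of which 675 kept the call, 238 lost it and 7 reversed in camera direction. DESeq2 size factors moved no count of changed genes by over 1.5 times. Unless stated, the cause was not tested where a value moved.

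Counts of changed genes are given in the order day 3 heads, day 40 heads, w1118 age and orco2 age, then gut orco2, gut per01 and the mutant guts against each other. With only the libraries of the 2 groups the counts were 347, 3113, 3816 and 1249 in heads and 5477, 1405 and 2331 in guts. The DESeq2 Wald test gave 1385 for day 3 heads, 159 for the interaction and 6554, 4385 and 4515 in guts, and dropping the count filter gave 1354 and 176 for the former pair. A log2 fold of at least 1 left 768, 801 and 1095 in the last 3 head comparisons by its construction. Without the 2 head libraries that held digestive transcripts the counts were 3817, 3580, 2835 and 4147 and the interaction 614, while its called lists were 4. Without per01 replicates 1 and 2, gut per01 gave 668 and the mutant guts 3703. Leaving out 1 library at a time gave 278 to 3246 for day 3 heads, 319 to 735 for day 40 heads, 447 to 936 for w1118 age, 771 to 4500 for orco2 age and 0 to 408 for the interaction. In guts it gave 590 to 3198, 973 to 2937 and 19 to 5211. Lists called, with the interaction after the other head comparisons, ran over 7 to 10, 11 to 13, 12 to 14, 14 to 16, 2 to 13, 13 to 17, 7 to 11 and 15 to 17. The overlap of both mutant guts was 2704 with DESeq2, the overlap of orco2 heads and guts 620, or 122 at a log2 fold of at least 1, and the overlap of age in both genotypes 503 at that fold.

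With an estimated correlation camera called 0 lists in each of the 8 comparisons. Fry called 1 list in day 3 heads, 0 in the interaction and 2 in gut per01, and between 10 and 15 elsewhere. A replicate block was fitted because the labels repeat the numbers, although the numbers were not found to pair samples (correlations of deviations from -0.40 to 0.15). With the replicate block the gut counts were 2070, 1294 and 42, and the overlaps 677 for both mutant guts and 171 for orco2 heads and guts.

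With the testis and accessory gland levels as covariates, the gut counts were 0, 109 and 9, where 2193, 3206 and 925 genes had an unadjusted p under 0.05, and the lists called were 4, 4 and 7. Among the orco2 genes called without covariates, 95.3% kept their sign and the median SE went from 0.362 to 0.575, so calls ended partly through wider errors. In orco2 per went from -2.56 ± 0.37 to -2.05 ± 0.77 and tim from -2.15 ± 0.28 to -1.27 ± 0.41. Reversed in orco2 were pim (-0.43), sa (-0.038) and the ribosomal (median 0.19), lipid (0.35) and testis (-0.013) lists, and between the mutants the Toll and Imd (-0.046) and ribosomal (-0.12) lists. The camera direction alone reversed for the accessory gland list in gut per01 and the testis list between the mutants, whose medians shrank to 0.41 and -0.0074 and kept their sign. The median alone changed sign for the oxidative phosphorylation list between the mutants (-0.031) and, without orco2 day 3 replicate 1, for the lipid list in the interaction (-0.018). The removal of marker levels from their own lists follows from how the fit is built.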

Other observations

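The tests of dilution, of a mixture, of clock phase in heads and guts (there also with covariates) and of photoreceptor loss were chosen after the results were seen.

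The neuropeptide, eye pigment, haemocyte and odorant receptor lists were called in no comparison.

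125 genes changed the same way in all 3 comparisons of orco2 with w1118, 70 higher and 55 lower of 10445, against 3.77 and 2.28 by chance. That chance level treats the 3 comparisons as independent and is too low. The head comparisons alone shared 438 higher and 188 lower of the genes tested in heads. Transposon insertions in heads were changed in 8.45% of 1101 tested at day 3 against 7.16% of other genes, in 9.81% against 13.3% at day 40, and with age in 6.45% against 16.7% in w1118 and 10.4% against 25.6% in orco2.

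Genes higher in the orco2 guts included accessory gland and testis genes. Within the w1118 and per01 groups, 46.05% of 1518 genes higher in orco2 followed the level of those markers (correlation of at least 0.8 over 6 libraries), against 23.1% of genes not called and 0.591% of lower genes. RNA of the reproductive tract in the gut samples is thus a candidate source of part of the higher genes, although a change in the gut itself stays open. Whether such RNA diluted the lower genes (median -1.45) stays open, as the digestive enzymes (median 1.04, SE 0.313) were called higher as a list. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and 1 split, the real one, gave the highest count in each gut comparison, 3573 against 0 for orco2, 2554 against 1051 for per01 and 726 against 0 between the mutants.

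The orco2 gut replicate 3 lay between replicates 1 and 2 in 99.3% of the 574 genes that differed at least 2-fold between them. The highest value of the other arrangements of the gut libraries was 71.6%. Genes higher in replicate 1 gave a share of 46.9% of replicate 1 and genes higher in replicate 2 gave 49.4%. A mixture of the RNA, libraries or reads of the other pair may therefore account for replicate 3, in which case the orco2 guts hold fewer than 3 independent samples and their p-values would be too small. No biological explanation was tested.

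The clock genes per, tim, vri and cwo were lower in orco2 in heads and guts. In heads Clk, which cycles opposite to per, was higher by 0.56 ± 0.19 at day 40 and 0.74 ± 0.19 at day 3 (adjusted p = 0.0923 and 0.0573, neither passing), consistent with a later phase or an earlier sampling time. In guts Clk went from -1.03 ± 0.26 to -0.43 ± 0.32 with the testis and accessory gland covariates, and as only the former lies over 2 SE below 0, this stays open there. Loss of photoreceptors was argued against, since the phototransduction median was 0.26 (SD 0.545) at day 3 while the 4 clock genes had -1.30. Strain background cannot be told from the mutation with 1 stock per genotype. Either may explain the 125 shared genes, and w, mutant in w1118, differs by strain. An effect of the orco2 mutation on the clock stays open as well, as 1 sampling time measures no rhythm.

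DNA of another strain carried along with the orco2 allele could change genes near Orco at both ages. Within 2 Mb of Orco 3.03% of 396 genes changed at both ages, against 5.17% of 11846 elsewhere (odds ratio 0.573, 95% interval 0.292 to 1.02, two-sided Fisher's exact p = 0.0621). The share was not higher near Orco, but such DNA further away was not tested.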
